A study of Drosophila melanogaster with 7 samples.

How the data were processed

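Gene expression was measured in pools of 400 first-instar larvae, 4 pools of the pof mutant and 3 of wild type, per the labels and the design text, with biotin-labelled target made from polyA RNA and 1 Affymetrix array per pool. Groups and replicate numbers were taken from the sample titles and source names. The allele and the genetic background of the stocks are not given in the sources used here.

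The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes, which name no version. RMA corrects background, quantile normalizes the arrays and summarises the probes of a probe set, so values are comparable between arrays of a probe set and not between probe sets, low signals are compressed, and true changes near the floor are understated. The values ran from 2.62 to 14.5 with nearly equal medians, as RMA log2 values do. No further normalization was applied, no pair of arrays was identical, and no detection calls were used here.

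Probe sets were named through the annotation table of the array platform, with symbols and chromosome arms updated by gene identifier from RefSeq (Release 6 assembly). 12394 of the 12443 probe sets with 1 gene matched an identifier there. Probe sets with several genes were tested but not named. No coordinates are printed, since no build is named for the array. For analyses per gene, the probe set with the highest mean over all arrays stood for the gene.

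Probe sets other than the 44 controls were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, pof mutant minus wild type, no covariate), with Benjamini-Hochberg adjustment over 13966 probe sets and a threshold of adjusted p under 0.05. Standard errors are limma's moderated ones. The chromosome 4 shift is the median log2 difference of its genes minus that of genes on the other arms, over genes with a mean log2 expression of at least 6, tested two-sidedly over all 35 splits of the 7 arrays into 4 and 3, which cannot give a p below 0.0286. Other arms and 19 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 5 arms and 19 lists, with an estimated correlation as an alternative. The lists cover dosage compensation, heterochromatin, ribosome, respiration, stress, immunity, detoxification, ecdysone, cell cycle, and markers of larval tissues and of other stages.

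The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names *Pof*, the 10 chromosome 4 genes with the smallest p (taken from those at the level limit of 6, which the rule did not spell out), up to 8 rises and 8 falls elsewhere past the threshold with 1 gene symbol and no overlap between groups, the MSL genes, and up to 4 genes with the smallest p of each other list discussed. Genes named outside it are marked as chosen after their values were seen. A measure of transcript evenness, the mean 3' minus 5' signal difference of the actin, eIF-4a and GAPDH controls, was added after the data were seen and used as a covariate in added alternatives.

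The alternatives were another quantile normalization, centring on genes outside chromosome 4, the level limits none, 6 and 7, and the replicate number as a block. Others were eBayes with trend and robust, array weights, leaving out probe sets ending in _s_at, _x_at or _a_at, and averaging probe sets per gene. Probe sets with other suffixes stayed in. The rest were a fold limit of 1.5, an adjusted p limit of 0.01 and the mean in place of the median. A fixed symbol list for chromosome 4 and leaving out each array in turn were also used.

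The steps were tested on simulated data drawn from the real means and spreads over 13966 probe sets. Of probe sets changed by 0.5, 1 and 2 on the log2 scale, 52.1%, 87.8% and 98.4% were recovered, and 4.34% of calls were false. A chromosome 4 shift of -0.3 over 21 genes was recovered as -0.29 on average, with the smallest possible p in 18 of 20 simulations. These simulations hold no difference in transcript evenness between arrays, and their noise was drawn independently for each probe set. On the real wild-type arrays the chromosome 4 median relative to the other arms varied with an SD of 0.21. The simulated shift varied with an SD of 0.048, so 18 of 20 overstates the power for chromosome 4 in these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.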

Results

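Whole first-instar larvae of *Drosophila melanogaster* carrying a mutation in *pof* were compared with wild-type larvae on 7 single-colour Affymetrix arrays, 4 of pof mutant and 3 of wild type, each hybridised with polyA RNA from a pool of 400 larvae of mixed sex. The submitters call the pools biological replicates. Of 14010 probe sets, 44 were array controls and 13966 were tested, of which 12443 named 1 gene, 327 named several and 1196 named none. These covered 10844 genes, 57 of them on chromosome 4. The median log2 expression was between 6.01 and 6.06 on every array, and pairwise correlations across probe sets ran from 0.970 to 0.995. The number of arrays limits the precision of all values given here.

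*Pof*, on chromosome arm 2R, encodes an RNA-binding protein that coats chromosome 4. Its transcript (probe set 141415_at) had a log2 expression of 3.44 ± 0.04 (SD, n = 4) in the mutant and 3.77 ± 0.13 (SD, n = 3) in wild type. All 4 mutant arrays (3.41 to 3.50) lay below all wild-type arrays (3.64 to 3.90), with a log2 difference of -0.33 ± 0.07 (SE). The difference did not pass the threshold over all probe sets (limma, adjusted p = 0.323; unadjusted p = 0.00263). The mean level of this probe set was at the 4.85 percentile of all probe sets, near the floor of the array in both groups, and where its probes lie relative to the mutation is not known. It is a weak check of the labels.

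The arrays differed in how evenly long transcripts were represented. The 3' minus 5' signal difference of the actin, eIF-4a and GAPDH control transcripts, averaged per array, was 1.92 to 2.19 on 4 arrays, and 3.22, 3.95 and 4.32 (log2) on pof mutant replicates 1 and 2 and wild type replicate 1. It did not separate the groups (pof mutant 2.87 ± 0.88, SD, n = 4; wild type 2.75 ± 1.35, SD, n = 3; exact two-sided permutation p = 0.857). It followed the first principal component, which held 56.8% of the variance (Pearson r = 0.925, exact permutation p = 0.00159, adjusted p = 0.0111 over 21 relations computed; Spearman rho = 0.82, exact permutation p = 0.0341, adjusted p = 0.143). Without wild type replicate 1 and pof mutant replicate 2, the arrays farthest from the median difference, r was 0.772 over the other 5 arrays. The second component, with 19.2% of the variance, had positive scores on all mutant arrays (0.561 to 12.2) and negative scores on all wild-type arrays (-12.2 to -5.45).

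**Figure D1:**
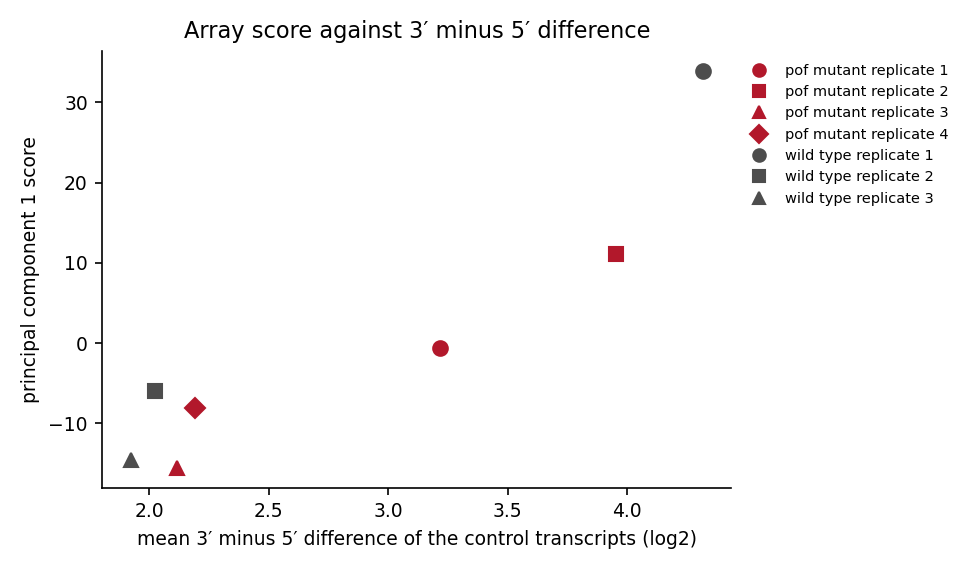
Score of each array on the first principal component (vertical axis, no unit) against the mean 3' minus 5' signal difference of the control transcripts (horizontal axis, log2); 1 point per array, red for pof mutant and grey for wild type. Wild type replicate 1 has the highest value on both axes (4.32 and 33.9), while the other wild-type arrays lie at or below 2.02 and -6.02.

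Only a few transcripts passed the threshold for a difference between pof mutant and wild type. In the mutant 4 named genes rose: *Cyp6a17* (152313_at, 2R) by 5.22-fold, *CG14419* (144419_at, X) by 4.21-fold, *Cyp4d1* (143572_at, X) by 3.06-fold and *CG6891* (145327_s_at, X) by 2.20-fold. The 3 named genes that fell were *Alp7* (147664_at, 2R), an alkaline phosphatase, *Cyp12d1-d* (154692_at, 2R), and *tko* (143018_at, X), a protein of the mitochondrial ribosome. Their wild-type levels were 7.16-fold, 7.15-fold and 2.12-fold those of the mutant. *Cyp6a17*, *Cyp4d1* and *Cyp12d1-d* encode cytochromes P450, enzymes that oxidise foreign compounds, hormones and lipids. *Cyp12d1-d* has a near-identical neighbour, *Cyp12d1-p*, whose RNA the probe set could also bind, so the value cannot be assigned to 1 of them alone.

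The fall of *Cyp12d1-d* had the smallest adjusted p, from 7.01 ± 0.29 (SD, n = 3) in wild type to 4.17 ± 0.26 (SD, n = 4) in the mutant, a log2 difference of -2.84 ± 0.17 (SE; limma, adjusted p = 0.00412). *Alp7* differed by -2.84 ± 0.21 (adjusted p = 0.00617) and *tko* by -1.09 ± 0.09 (adjusted p = 0.0109). *CG14419* differed by 2.07 ± 0.15 (adjusted p = 0.00617), *CG6891* by 1.14 ± 0.10 (adjusted p = 0.0139), *Cyp6a17* by 2.39 ± 0.23 and *Cyp4d1* by 1.61 ± 0.16 (both adjusted p = 0.0177). The other probe set of *CG6891* had a difference of 0.77 ± 0.11 (adjusted p = 0.12). In all, 9 of 13966 probe sets passed limma's threshold (adjusted p under 0.05), 5 higher and 4 lower in the mutant, and 759 had an unadjusted p under 0.05 where 698 are expected by chance. The remaining probe sets past the threshold, 143303_at (-1.27) and 154506_at (0.75), name no gene.

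The number of calls depended on single arrays. It was 0 without pof mutant replicate 1, 5 without pof mutant replicate 2 or 3, 2 without wild type replicate 2, and 34 (10 higher, 24 lower) without wild type replicate 1, the array with the largest 3' minus 5' difference. With that difference as a covariate, chosen after the data were seen, 86 probe sets passed (46 higher, 40 lower), all 9 among them. After another quantile normalization the split was 5 higher and 7 lower, and after centring each array on genes outside chromosome 4 it was 5 higher and 8 lower.

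**Figure D2:**
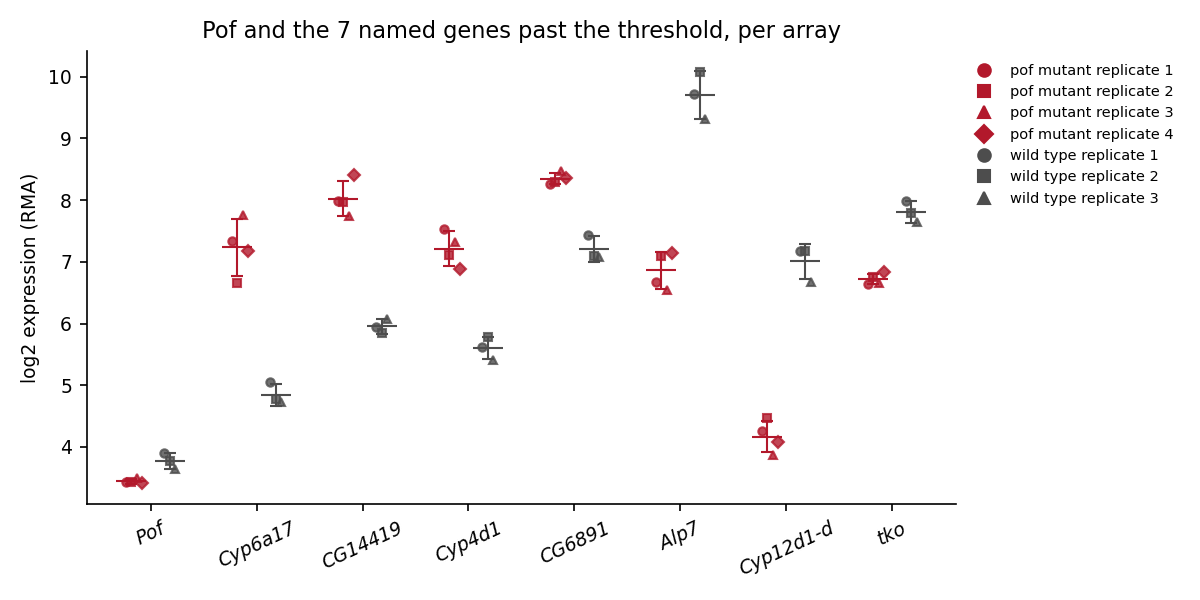
Log2 expression of *Pof* and of the 7 named genes past the threshold (vertical axis) on each array, red for pof mutant and grey for wild type; horizontal bars are group means and whiskers SD. The groups do not overlap for any of these genes, and *Cyp12d1-d* and *Alp7* show the widest gaps (both -2.84).

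The comparison the mutant was made for concerns chromosome 4. Its 21 genes with a mean log2 expression of at least 6 were at nearly the same level in both groups. Their median log2 difference, pof mutant minus wild type, was -0.02 against -0.01 for 5854 genes of the other arms, a shift of -0.013 (exact two-sided permutation p = 0.886; camera p = 0.554). Of these genes 15 (71.4%) had a lower mean in the mutant, as did 3044 (52%) of the others (Fisher's exact p = 0.0831). That count followed single arrays, from 16 of 21 without wild type replicate 1 (Fisher's exact p = 0.0272) or pof mutant replicate 3 (p = 0.0268) to 6 of 21 without wild type replicate 3 (p = 0.0469), and was 10 with the covariate. Over all 57 chromosome 4 genes, with no level limit, 42 (73.7%) had a lower mean, against 57.8% of the others (Fisher's exact p = 0.0154; camera p = 0.0183; exact permutation p of the shift of -0.045 = 0.6), but with the covariate 37 of 57 were lower (Fisher's exact p = 0.347; camera p = 0.122). No chromosome 4 gene passed limma's threshold, and 5 of the 57 had an unadjusted p under 0.05, all lower in the mutant. Of the 21 this was 1, *CG33941*, with a log2 difference of -0.32 ± 0.10 (SE; limma, adjusted p = 0.634). The other 4 lay under a level of 6 and are named after their values were seen: *Syt7* (-0.28 ± 0.08), *Asator* (-0.26 ± 0.09), *yellow-h* (-0.29 ± 0.11) and *CG1674* (-0.25 ± 0.11), with limma adjusted p of at least 0.608. The transcription factor genes *ey* (-0.07 ± 0.06) and *toy* (-0.12 ± 0.12), both of the Pax6 type, lay below 0 by about their standard errors. *Rad23* (-0.10 ± 0.11), *dati* (-0.06 ± 0.09), *ATPsynbeta* (-0.09 ± 0.15) and *CG11076* (-0.13 ± 0.21) had lower means too, and *Mpv17* (0.23 ± 0.11), the lipid transport gene *apolpp* (0.29 ± 0.15) and *Taf3* (0.04 ± 0.06) higher ones. The adjusted p of these 9 genes was at least 0.951.

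Per array, the median of chromosome 4 minus that of the other arms was -0.0022 ± 0.08 (SD, n = 4) in the mutant and -0.0084 ± 0.21 (SD, n = 3) in wild type. The mean difference of 0.0061 had an interval of -0.27 to 0.33 (97.1%, from inverting the exact permutation test), or 0.832-fold to 1.26-fold, so a uniform fall of chromosome 4 to less than 0.832 of its wild-type level was outside it. This per-array value ran against the 3' minus 5' difference of the controls (Pearson r = -0.853, exact permutation p = 0.00694, adjusted p = 0.0243 over the 21 relations; Spearman rho = -0.89, exact permutation p = 0.0123, adjusted p = 0.0861; r = -0.68 without the 2 farthest arrays). It was lowest on wild type replicate 1 (-0.22) and highest on wild type replicate 3 (0.20). The sign of the shift turned with the array left out, from -0.10 without wild type replicate 1 to 0.07 without wild type replicate 3, and it was 0.0057 with the covariate.

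**Figure D3:**
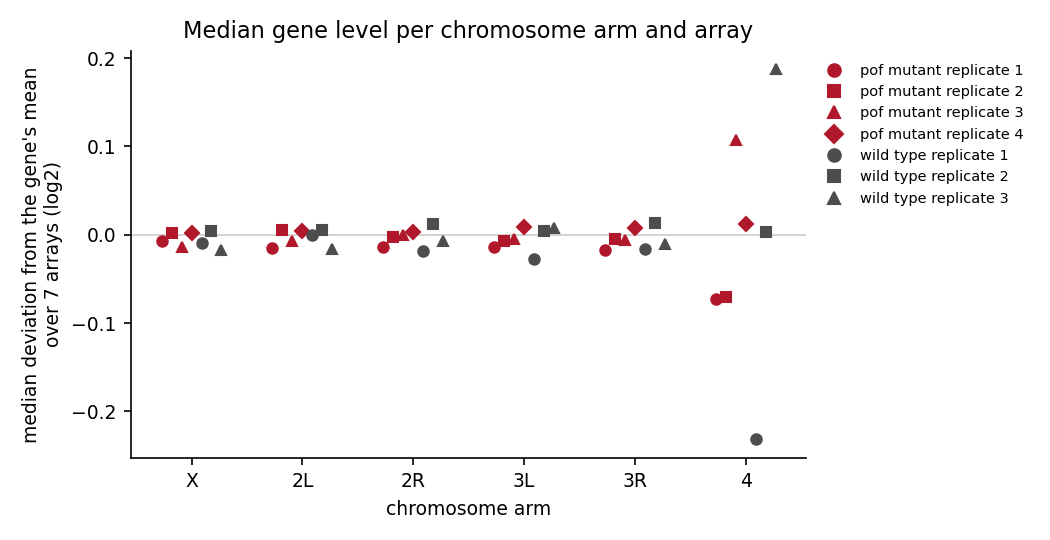
Median deviation of genes from their mean over the 7 arrays (vertical axis, log2) for each chromosome arm (horizontal axis), with 1 point per array, red for pof mutant and grey for wild type. Arms X, 2L, 2R, 3L and 3R stay close to 0 on every array. Chromosome 4 ranges from -0.23 on wild type replicate 1 to 0.19 on wild type replicate 3, with the mutant arrays between. Its medians rest on 21 genes and those of the other arms on 991 to 1453 genes each, so the spreads cannot be compared directly.

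None of the 5 other arms differed from the rest. The X chromosome, which has its own dosage compensation in males, had a shift of 0.0023 over 1064 genes (limma's camera, adjusted p = 0.929 over the 5 arms), and the shifts of 2L, 2R, 3L and 3R were 0.0057, 0.0037, -0.0075 and -0.0065, with no unadjusted p under 0.05. The list of the MSL complex, which carries out that compensation, and its roX RNAs had 6 of 8 genes measured, with no roX RNA among them. None passed limma's threshold over all genes or adjusted over the list alone. Only *msl-2* (6.48) reached a mean level of 6, and the others lay at 4.74 to 5.35, where changes are understated. *msl-3* (-0.16 ± 0.07) was the 1 member with an unadjusted p under 0.05 (limma, adjusted p = 0.905). *mof* (-0.17 ± 0.09), *mle* (-0.12 ± 0.12), *msl-2* (-0.02 ± 0.06), *msl-1* (-0.0021 ± 0.05) and *Clamp* (0.04 ± 0.30) lay within or close to 2 standard errors of 0. Among 18 measured HP1 and heterochromatin factors none passed either adjustment and none had an unadjusted p under 0.05; *wde* (0.20 ± 0.12) and *Su(var)2-HP2* (-0.12 ± 0.08) had the smallest p. Their list had a median of -0.01 (limma's camera, adjusted p = 0.896).

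Detoxification genes changed in both directions. Of 49 measured genes of cytochromes P450, glutathione S-transferases and UDP-glycosyltransferases, 3 passed limma's threshold over all probe sets (2 higher, 1 lower), and 12 passed adjusted over the list alone, 5 higher and 7 lower. Besides *Cyp12d1-d*, *Cyp6a17* and *Cyp4d1*, the smallest p belonged to *Cyp6a23*, which lies next to *Cyp6a17* in the Release 6 annotation. It went from 7.73 ± 0.40 (SD, n = 3) in wild type to 5.70 ± 0.38 (SD, n = 4) in the mutant, a log2 difference of -2.02 ± 0.24 (SE; limma, adjusted p = 0.0529 over all probe sets and 0.000498 over the list alone). For the list as a whole no shift one way was found, with 19 members higher and 30 lower and a median of -0.06 (camera, adjusted p = 0.831), though with array weights it passed as lower (-0.11, camera, adjusted p = 0.048).

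**Figure D4:**
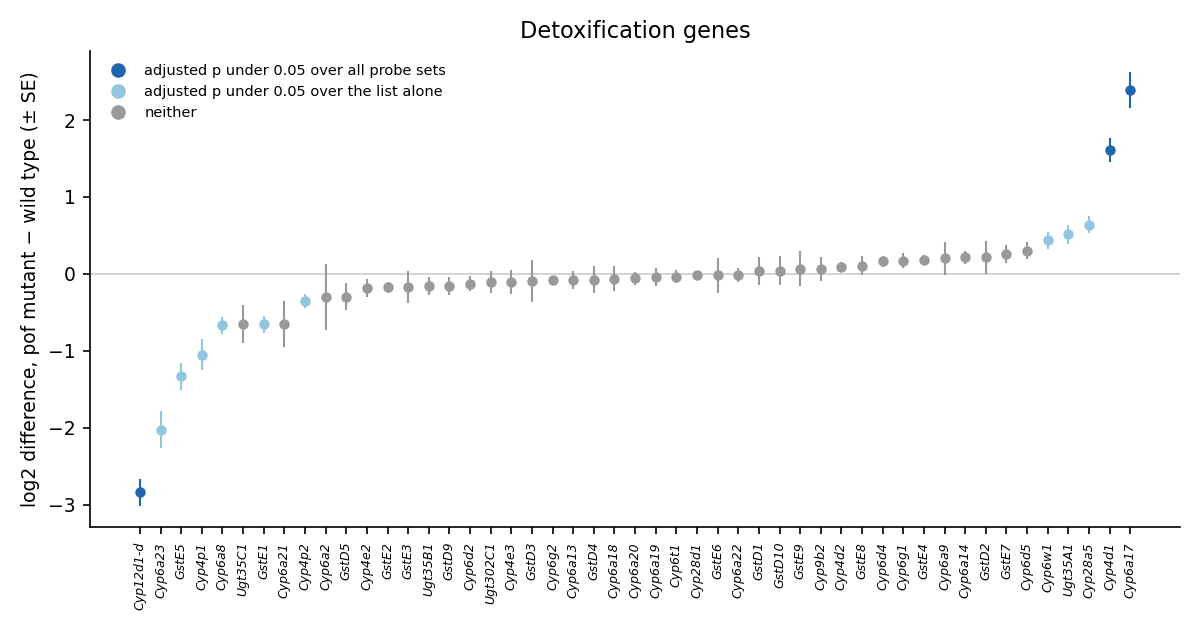
Log2 difference, pof mutant minus wild type, with its standard error (vertical axis) for the 49 detoxification genes in order of the difference (horizontal axis); colours mark genes past the adjusted threshold over all probe sets, over the list alone, or neither. The values run from -2.84 for *Cyp12d1-d* to 2.39 for *Cyp6a17*, with most genes near 0.

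Genes of digestion and of the cytosolic ribosome were the only lists of 19 past the threshold of limma's camera test, and neither call held with an estimated correlation. Of 44 midgut digestion genes 27 were higher and 17 lower in the mutant, with a median difference of 0.10 (adjusted p = 0.0287 with the preset correlation; adjusted p = 0.956 with an estimated correlation). Pof mutant replicates 1 and 3 had per-array medians of 0.20 and 0.20, while replicates 2 and 4 (-0.13 and -0.07) lay within the wild-type range (-0.15 to 0.02). The call ended without pof mutant replicate 1 (adjusted p = 0.689) or 3 (0.379) and without wild type replicate 1 (0.179) or 3 (0.0786). It also ended after another quantile normalization (0.209) and at a level of at least 6 (0.0547) or 7 (0.237). With array weights the median turned to -0.0099 (0.494). The call held after centring on genes outside chromosome 4 (0.0142). It also held with the replicate block (7.32e-05), a fit that cannot use pof mutant replicate 4, which has no wild-type array of its number. Leaving out that array without a block gave the same median (0.12) and held too (0.000729). None of the 44 genes passed over all probe sets, 16 had an unadjusted p under 0.05, and 7 passed adjusted over the list alone, 5 higher and 2 lower. The trypsin gene *betaTry* differed by 1.37 ± 0.22 (SE; adjusted p = 0.0147 over the list alone), *LManI* by 0.53 ± 0.10, and the Jonah proteases *Jon44E* and *Jon25Biii* by 0.65 ± 0.14 and -0.58 ± 0.13. Of 26 measured ribosomal protein genes 25 were higher, by a median of 0.10 (adjusted p = 2.96e-06; adjusted p = 0.658 with an estimated correlation). *RpS18* (0.30 ± 0.09), *RpS21* (0.28 ± 0.09), *RpLP1* (0.25 ± 0.10) and *RpL40* (0.19 ± 0.10) had the smallest p. None of the 26 passed over all probe sets or over the list alone, and 3 had an unadjusted p under 0.05. The ribosomal median per array was 0.11 and 0.10 on pof mutant replicates 1 and 2, -0.015 and 0.00047 on replicates 3 and 4, and -0.025 to -0.055 on the wild-type arrays. With the covariate the median difference was again 0.10 (camera, adjusted p = 2.88e-06, or 0.96 with an estimated correlation). After another quantile normalization it was 0.05, and the ribosomal call ended (camera, adjusted p = 0.209 with the preset correlation).

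Metabolic and immune genes gave a few calls adjusted over their lists alone, and none over all probe sets (limma). In the fat body list, 4 of 15 genes passed in this way. *mdy*, an enzyme of triglyceride synthesis, was higher by 0.57 ± 0.10 (SE) and *FASN1*, a fatty acid synthase, by 0.37 ± 0.09, while the clotting gene *fon* (-0.37 ± 0.07) and the trehalose synthesis gene *Tps1* (-0.52 ± 0.16) were lower. The other probe set of *mdy* had a difference of 0.02 ± 0.15. In the immune list, 2 of 13 passed: *PGRP-SC2*, an enzyme that cleaves peptidoglycan, at -0.87 ± 0.17 and the NF-kB factor *Rel* at 0.67 ± 0.18. *Mtk* (0.35 ± 0.14) and *Bbd* (0.11 ± 0.06) did not pass. Neither list shifted as a whole (adjusted p = 0.896 for fat body and 0.574 for immune genes).

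The remaining lists mark tissues, stages and cell functions, and none had a member past the threshold over all probe sets or over the list alone, while at most 2 genes in any of them had an unadjusted p under 0.05. Cuticle and trachea genes had a median of -0.10 (6 of 26 higher; camera, adjusted p = 0.284), with *Cpr49Ac* at 0.44 ± 0.13, *kkv* at -0.21 ± 0.07, *TwdlE* at -0.18 ± 0.08 and *Lcp65Ac* at 0.39 ± 0.21. The median was 0.10 for muscle (adjusted p = 0.574), 0.07 for mitochondrial respiration (0.284), 0.05 for heat shock and unfolded protein genes (0.602), -0.07 for cell cycle and replication (0.31), -0.07 for the MSL list (0.337), -0.03 for neuron (0.896) and 0.03 for genes in pericentromeric heterochromatin (0.896). It was -0.02 for the ecdysone response (0.919), -0.01 for haemocyte (0.896), -0.02 for maternal and early embryo (0.831), -0.02 for ovary and adult female (0.919) and -0.03 for testis genes (0.896). Without wild type replicate 1 the medians of muscle and respiration turned to -0.14 and -0.09 (adjusted p = 0.134 and 0.179). Heterochromatin factors, neuron and the maternal list had a median below 0 while camera's direction was up. Per-array medians of 6 lists followed the 3' minus 5' difference by adjusted Pearson p, but only 2 of them, the immune and the maternal and early embryo lists, by adjusted rank p. Among the 6 were mitochondrial respiration (Pearson r = -0.93, exact permutation p = 0.00278, adjusted p = 0.0146; Spearman rho = -0.75, exact permutation p = 0.0663, adjusted p = 0.174; r = -0.804 without the 2 farthest arrays) and maternal and early embryo genes (r = 0.893, exact permutation p = 0.000198, adjusted p = 0.00417; rho = 1, exact permutation p = 0.000397, adjusted p = 0.00833; r = 0.854 without the 2 farthest arrays). The others were the immune (Spearman rho = 0.964, adjusted exact permutation p = 0.0292), muscle (-0.679, 0.23), ovary and adult female (0.821, 0.143) and testis lists (0.786, 0.144).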

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

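Of the tests in this part, those of the first principal component were chosen after the result was seen. Groups of 3 were not examined for outlying arrays, so only the 4 mutant arrays were. Over 70 sets of 4 mutant values, 5 had 1 array farther from the rest than Dixon's 95% limit, where chance gives about 1 in 20 (3.5). *toy* was 7.99 on pof mutant replicate 3 against a median of 7.57 on the other 3 arrays, and *kkv* was 6.81 on replicate 4 against 6.63. *Su(var)2-HP2* was 5.02 on replicate 1 against 5.15. On replicate 2, *HP1b* was 7.50 against 7.63 and *Bbd* 3.87 against 3.82. None of the 44 control probe sets had all mutant arrays above all wild-type arrays with a limma adjusted p under 0.05, and 3 had an unadjusted p under 0.05 in either direction.

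A wider pattern is the position of wild type replicate 1, which lies apart on the first principal component at 33.9. The other wild-type arrays, at -6.02 and -14.6, lay within the range of the mutant arrays (-15.6 to 11). A difference between the groups was not excluded by the distance of this array (40.0 to the nearest other wild-type array), since the array was picked for that distance. A loss of signal from the 5' ends of transcripts, as from partly degraded RNA or short cDNA, may account for it, since the 3' minus 5' difference of the control transcripts follows the component over the 7 arrays (Pearson r = 0.925, exact permutation p = 0.00159, adjusted p = 0.0111; Spearman rho = 0.821, exact permutation p = 0.0341, adjusted p = 0.143). The median deviation of maternal and early embryo genes was also highest there (0.15, against -0.04 and -0.06 on the other wild-type arrays). So were those of ovary and adult female genes (0.17) and of testis genes (0.15). An earlier stage of the larvae in that pool stays open as a biological explanation and was not tested apart from loss of 5' signal. These lists do not single it out, since embryo and adult markers were high together. The chromosome 4 median followed the same measure, so both readings apply to its spread between wild-type arrays too.

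Chance could not be excluded for the number of probe sets called. Of the 35 splits of the 7 arrays into 4 and 3, 2 gave as many calls as the real one (9), itself included. The higher one, with 17 calls, set pof mutant replicates 3 and 4 and wild type replicates 2 and 3 against the other arrays, which are the 3 with the high 3' minus 5' difference, so it follows that technical measure. With the measure as a covariate the real split gave 86 calls, and again 2 splits gave as many; the other, with 134, set pof mutant replicate 4 together with the wild-type arrays. For gene lists 28 of the 35 splits gave 2 or more past the threshold, up to 6, so the number of lists called is within what the splits give. That count covers lists of any kind and does not test the ribosomal or midgut list by itself. Exact permutation of the list median gave unadjusted p = 0.0857 for ribosomal and 0.314 for midgut genes. Counts of chromosome 4 genes and of other arms past the threshold were 0 in the real split and in all 35, which excludes nothing.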

How the results depend on the processing

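The alternatives with the 3' minus 5' covariate were added after the data were seen; the others were planned. The count of 9 probe sets was 4 at a level of at least 7, 4 at adjusted p under 0.01, 86 with the covariate and 1200 with array weights, whose estimation did not converge and gave wild type replicate 2 a weight of 17.1. With 1 array left out it ran from 0 to 34. The replicate number as a block gave 2 probe sets, and the labels do not say that the numbers pair arrays. The block fit also cannot use pof mutant replicate 4 for the group difference, since no wild-type array has its number. Deviations of same-numbered arrays correlated at 0.245, -0.571 and 0.559, and 1 of 3 wild-type arrays correlated best with its own number. Wild type replicate 1 correlated best with pof mutant replicate 2 (0.69), and these 2 arrays have the largest 3' minus 5' differences. The correlations follow that measure and cannot decide whether same-numbered pools were handled together. Gene lists past the threshold went from 2 to 0 after another quantile normalization, 1 at a level of at least 6 or 7, 0 with an estimated correlation (also with the covariate), and 0 by exact permutation of medians, which with 19 lists can hardly pass; the range with 1 array left out was 1 to 4. Respiration passed with the covariate (0.09, adjusted p = 0.00797), without wild type replicate 2 (adjusted p = 0.00246) and without pof mutant replicate 2 (0.0315), muscle without wild type replicate 3 (0.30, adjusted p = 0.0104), cuticle and trachea without wild type replicate 2 (-0.14, adjusted p = 0.0412) and detoxification with array weights (-0.11, adjusted p = 0.048); each of these calls used the preset correlation. The chromosome 4 shift of -0.013 became 0.0057 with the covariate and ran from -0.096 to 0.070 with 1 array left out; without a level limit it was -0.045 over 57 genes (exact permutation p = 0.6, camera p = 0.0183), and with the covariate -0.041 (camera p = 0.122; Fisher's exact p = 0.347 for the share of lower genes, 0.0154 before). No alternative took its permutation test past the threshold; where 1 array is left out the smallest p possible is 0.1 or 0.0667, and 0.25 with the block, so that test could not pass there. Camera also gave p = 0.0344 without wild type replicate 1, and the share of lower genes gave Fisher's exact p = 0.0332 with the symbol list. With array weights, 2 chromosome 4 genes passed, and *Pof* passed at -0.33 (limma, adjusted p = 0.00403; range over its alternatives 0.00403 to 0.881). Signs also turned for genes close to 0: *msl-1* after quantile normalization (0.019), *Clamp* with the replicate block (-0.033), and *Clamp* (-0.072), *mle* (0.049) and *ATPsynbeta* (0.0017) with array weights. With 1 array left out, *msl-1* ran from -0.0042 to 0.00076, *msl-2* from -0.038 to 0.0029, *Clamp* from -0.28 to 0.29, *dati* from -0.118 to 0.015, *ATPsynbeta* from -0.189 to 0.075, *mle* from -0.213 to 0.037 and *CG11076* from -0.372 to 0.00015. The cause of these shifts was not tested, except where fewer probe sets or arrays entered. The 7 named genes past the threshold kept their sign under every alternative; 5 lost the call with the block, and 23 of 49 values with 1 array left out lost it. Signal near the floor, as for *Pof*, limits what could be seen.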

Other observations

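All tests in this part were chosen after the values were seen. With the 3' minus 5' difference as a covariate, further genes passed limma's threshold, named here after their values were seen. The metallothionein gene *MtnB* was lower in the mutant by a log2 difference of -0.93 ± 0.06 (SE; adjusted p = 0.00123), while *MtnA*, of the same family, was higher by 0.56 ± 0.07 (adjusted p = 0.0172). *SrpRalpha*, the signal recognition particle receptor subunit, was lower by -1.21 ± 0.08 (adjusted p = 0.00123) by 1 probe set, while its other probe set had a difference of 0.0028 ± 0.06. *Cyp9c1* (-1.58 ± 0.13), *GstE5* (-1.36 ± 0.11) and *Cyp4p1* (-1.02 ± 0.12) were lower and *Cyp28a5* (0.65 ± 0.11) higher. Without the covariate none of these genes passed, with limma adjusted p from 0.0529 (*GstE5*) to 0.638 (*MtnA*), and 0.412 for *MtnB*. Mutant and wild-type arrays overlapped for *MtnA*. In the covariate fit another split of the arrays gave 134 calls, more than the 86 of the real one. Of 49 detoxification genes 9 passed over all probe sets in this fit, and 18 adjusted over the list alone. Over all probe sets 3 of 44 midgut, 1 of 13 immune and 1 of 15 fat body genes passed as well.

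Detoxification, midgut digestion and fat body genes differed between mutant and wild type in either direction more often than other genes. Each of the 19 lists was tested for the share of genes with an unadjusted p under 0.05, and 3 passed: 16 of 49 detoxification (32.7%, Fisher's exact test, adjusted p = 5.98e-08), 16 of 44 midgut (36.4%, adjusted p = 1.95e-08) and 5 of 15 fat body genes (33.3%, adjusted p = 0.00712), across genes, which are not independent replicates. The ratio of mean absolute limma t to that of all genes was 2.84 for detoxification, 1.99 for midgut and 2.06 for fat body. For these lists and the immune one it was higher than in any other of 35 splits of the arrays, where detoxification reached at most 1.74, so this is not particular to detoxification. The real split was thus the highest for 4 of 19 lists. Chance is not excluded, since 1 of 35 is the smallest share possible and the test was made after the calls were seen. For detoxification, the ratio was 2.54 with the covariate. The mean 3' minus 5' difference was nearly equal in the groups (2.87 in the mutant, 2.75 in wild type). The covariate could therefore hardly change the ratio, and its fit does not decide on loss of 5' signal. Without wild type replicate 1, the array with the largest 3' minus 5' difference, the ratio was 2.83, so it does not rest on that array alone. RNA of *Cyp6a17* binding probes of its neighbour *Cyp6a23* would move both the same way, but they moved in opposite directions, each by at least 8.32 standard errors. A difference between the stocks in regulatory variants, food or handling stays open and cannot be set apart from the mutation here, so that an effect of *pof* on these genes is a hypothesis only.

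The genes with the smallest p lay on chromosome 3 less often than other genes. Of 54 genes with an unadjusted p under 0.001, 11 (20.4%) lay on 3L or 3R, against 44.9% of 10742 genes (Fisher's exact p = 0.000277, across genes, which are not independent). The share was 30.8% of 130 genes with the covariate (Fisher's exact p = 0.000995). Of the 54 genes 9 lay on X, 17 on 2L and 17 on 2R, and of the 130 it was 14, 30 and 46. These counts had no level limit. Genes per arm were counted only at a level of at least 6 (1064 on X, 991 on 2L and 1196 on 2R). Shares per arm can therefore not be read from these numbers. In both fits X gave fewer such genes than either arm of chromosome 2, and single arms were not tested. By contrast, of the genes at a level of at least 6 that passed limma's adjusted threshold, 4 lay on X and 2 on 2R. A difference in genetic background on X and chromosome 2, as when a chromosome of another stock is carried along, is a candidate explanation. These counts do not single out chromosome 2. Clusters of detoxification and protease families were part of the low share on chromosome 3. Without them the share was 25.6% of 43 genes against 45.1% (Fisher's exact p = 0.0131), and with the covariate 35.4% of 113 (p = 0.0455, close to the threshold), so they do not account for all of it, by a narrow margin in the covariate fit. Sequence differences under the probes stay open: of the further probe sets of these genes only 2 reached a level of 6, and 1 moved the same way. Splits of the arrays do not settle it, as 8 of 35 gave a share on chromosome 3 as low, and only 4 had 10 or more such genes.

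Among the 40 measured genes nearest to *Pof* on 2R, 4 had an unadjusted p under 0.01, namely *Cyp9c1* (-1.62 ± 0.28), *CG3663* (-0.37 ± 0.08), *Adck1* (-0.34 ± 0.09) and *GstE12* (0.61 ± 0.12). The median window of that size on 2R held 1 such gene, and 173 of 2136 windows held 4 or more. Chromosome 4 genes under a log2 level of 6 had a median difference of -0.08 over 36 genes, against -0.03 for 4888 genes of other arms at that level (exact permutation p = 0.571).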
